A study of Homo sapiens with 9 samples.

How the data were processed

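Gene expression was measured on 9 Affymetrix whole-transcript arrays, 3 per group, from the H9 human embryonic stem cell line carrying a doxycycline-inducible TCF7L1 transgene. Per the labels, total RNA was isolated with Qiagen RNeasy reagents, and fragmented single-stranded DNA was labelled with biotin before hybridisation. The deposited values are intensity per probe set on a linear scale, and per the submitters' processing notes they came from Affymetrix Expression Console 1.1.1 with the PLIER 2.0 summary. The background correction and between-array normalization behind them are not given in the sources used here. Deposited values ran from 2.47e-05 to 57102, with array medians from 200.4 to 216. For arrays of this kind their number, 3 per group, limits the precision.

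The array annotation listed 33297 probe sets, of which 19460 had 1 gene symbol, 1754 had several and 12083 had none listed. Of the probe sets with 1 symbol, 19429 were matched by gene number to a gene listing of assembly GRCh38.p14 and took its current symbol, and 31 kept the symbol of the annotation. Each gene was represented by the probe set with the highest mean over the 9 arrays, which left 18417 genes, 769 of them with more than 1 probe set. POU5F1 and NANOG were represented only on probe sets with several symbols and are not analysed here. Probe sets shared between near-identical genes cannot separate them, so values of LEFTY1, CYP2B6 and the metallothioneins are uncertain in this respect.

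Values were converted to log2(value + 16), so that a fold change is on that scale and understates the change of dim genes. The array medians spanned 0.10 on the log2 scale, above the limit of 0.1 fixed for leaving them as deposited, and the arrays were quantile-normalized. Quantile normalization gives the brightest probe set of each array a common value, which compresses changes at the top of the scale. It also removes the spread between arrays where a bright gene holds the same rank, as for EOMES and APLNR in PS medium (log2 SD 0). All 9 arrays were fitted with 1 mean per group in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with a trend), with 6 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over 18417 genes at a threshold of 0.05. Files were read with the R package data.table, version 1.17.8, and plots were drawn with matplotlib 3.10.9 under Python 3.11.15. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

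Gene groups were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over lists within each comparison, and again with a correlation estimated per list. The 28 lists held 605 distinct genes, 545 of them measured, and 27 lists were tested, because no member of the mitochondrially encoded list was measured. The lists overlapped, with 676 entries for the 605 genes, so calls of lists that share members are not separate evidence. For example, EOMES, GATA6, GATA4 and CER1 were in both the primitive streak and the definitive endoderm list. The tested lists covered core and naive pluripotency, primitive streak, definitive endoderm, mesoderm, neuroectoderm, and amnion and trophectoderm. Signalling lists covered Wnt targets, Wnt ligands, Wnt receptors and inhibitors, TCF/LEF factors with co-repressors, Nodal/Activin, BMP and FGF/ERK. The others covered epithelial and mesenchymal genes, cell cycle, p53, ATF4 stress, nuclear oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, interferon response, immediate early genes, HOX genes, fibroblasts, and endothelium and blood. The lists, tests, designs, named-gene rule and alternatives were fixed before the data were examined.

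The named genes of each comparison were a fixed set (TCF7L1, POU5F1, NANOG, SOX2, TBXT, MIXL1, EOMES, SOX17, AXIN2, LEF1 and SP5), then the 6 largest rises and 6 largest falls past the threshold whose 3 and 3 arrays did not overlap, without genes lacking a standard symbol, and up to 4 members of each list with the largest changes past the threshold.

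Replicate numbers were checked for pairing from the correlation, over genes, of deviations from the group means. Arrays of the same number correlated at 0.245, 0.428 and 0.246 between PS medium with doxycycline and PS medium alone, and at 0.246, 0.309 and 0.297 between PS medium with doxycycline and untreated cells. All of these exceeded 0.1, so the numbers were taken to pair the samples in these comparisons, on the basis of the data and not of the labels. The fit without the replicate number was the planned one and was kept, with the replicate number as a block as an alternative.

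The procedure was tested on simulated data for PS medium with doxycycline against PS medium alone, over 18417 genes. It recovered 98% of 100 genes changed by 2-fold and 100% of 100 genes changed by 4-fold, with 8 false calls among unchanged genes. A list of 25 genes shifted by 0.5 on the log2 scale was called, and 0 of 100 unshifted lists were called by camera. The simulated genes varied independently of each other, so false calls of lists whose members vary together were not tested.

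Alternatives were values as deposited, median centring, log offsets of 1 and 64, leaving out the dimmest 30% of genes, all probe sets or their mean per gene, a fit of the 2 groups alone, other variance moderation, the replicate block, another fold minimum, fry for the lists, and leaving out each array in turn. Probe sets with several symbols or none listed were left out of the comparisons because no single gene could be named for them.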

Results

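H9 is an established human embryonic stem cell line, and the H9 derivative used here carries a TCF7L1 transgene that doxycycline switches on. TCF7L1 is a DNA-binding factor of the TCF/LEF family that mostly represses targets of Wnt signalling. RNA was profiled from untreated cells in mTeSR1, a medium that maintains pluripotency, from cells kept 48 h in a primitive streak differentiation medium (PS medium), and from cells kept in PS medium with 1 ug/ml doxycycline for 48 h, with 3 arrays per group. The primitive streak is the embryonic structure from which mesoderm and endoderm arise. The stated purpose was to find putative TCF7L1 target genes by over-expression. Correlations across genes were 0.995 to 0.997 among untreated arrays, 0.989 to 0.995 among PS arrays and 0.989 to 0.994 among doxycycline arrays, and 0.966 to 0.977 between the last 2 groups. The first principal component, with 59.2% of the variance, separated untreated arrays from the rest, and the second, with 25.5%, separated PS medium with doxycycline from PS medium alone.

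TCF7L1 itself (probe set 8043114) was measured first, since it is the gene that doxycycline was used to induce. Its deposited intensities were 3718, 3878 and 3572 in untreated cells, 1275, 1542 and 1611 in PS medium, and 13100.2, 12433 and 2699 in PS medium with doxycycline. With doxycycline it was 5.24-fold higher than in PS medium alone (log2 difference 2.39 ± 0.47, SE, n = 3 per group, limma adjusted p = 0.00464). Replicate 3 of the doxycycline group was 1.83 times the PS mean and 0.725 times the untreated mean, and without it the rise was 8.79-fold (log2 3.14, adjusted p = 3.90e-08). TCF7L1 was 2.55-fold lower in PS medium than in untreated cells, which missed the threshold (log2 -1.35 ± 0.47, adjusted p = 0.0502). That SE pools the spread of all 3 groups. The log2 SD was 1.29 with doxycycline, 0.17 in PS medium and 0.06 in untreated cells. The difference between PS medium and untreated cells passed without doxycycline replicate 1 (adjusted p = 0.0377), 2 (0.0394) or 3 (1.01e-06). It also passed on values as deposited (0.0496), without the dimmest genes (0.0449), in a fit of the 2 groups alone (6.49e-06) and with the replicate block. Against untreated cells, TCF7L1 with doxycycline differed by 1.04 ± 0.47 on the log2 scale (adjusted p = 0.124), and by 1.78 without doxycycline replicate 3 (adjusted p = 4.68e-07).

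**Figure D1:**
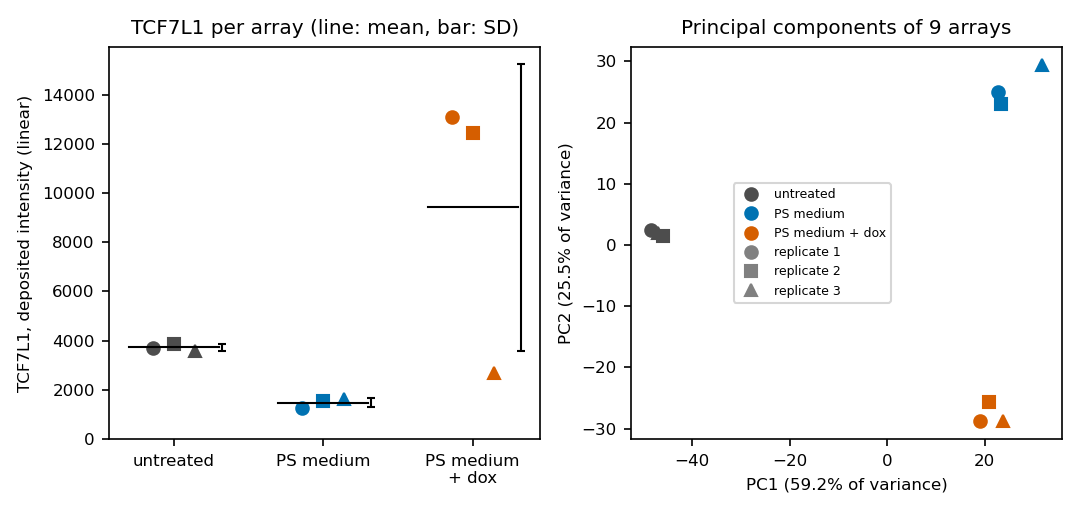
Left, deposited TCF7L1 intensity of each of the 9 arrays by group, with a line at the group mean and a bar of 1 SD; doxycycline replicates 1 and 2 lie at 13100.2 and 12433 and replicate 3 at 2699. Right, the 9 arrays on the first (59.2%) and second (25.5%) principal components of the normalized log2 values.

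The comparison of PS medium with untreated cells asks what the differentiation medium changed without induction of the transgene. GATA6, an endoderm and heart factor, rose 261-fold (log2 8.03 ± 0.16, SE, n = 3 per group, adjusted p = 4.64e-10). It was dim in untreated cells, and its fold was 79.7 with a log offset of 64 and 996 with an offset of 1. GATA4, a related factor, rose 167-fold. CER1, a secreted antagonist of Nodal and BMP, rose 164-fold, and HAND1, a factor of extraembryonic and heart mesoderm, rose 106-fold. EOMES, a T-box factor of the streak, rose 115-fold, and APLNR, the apelin receptor, rose 102-fold. On values as deposited, which do not compress the brightest genes, those folds were 239 for EOMES and 165 for APLNR. MIXL1, a streak homeobox factor, rose 76.2-fold (log2 6.25 ± 0.12), SOX17, an endoderm factor, rose 15.4-fold (3.95 ± 0.19), and TBXT, the streak and notochord factor brachyury, rose by 1.68 ± 0.22 on the log2 scale (adjusted p = 0.000209).

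The largest falls included LRAT, which esterifies retinol (18.8-fold lower), IDO1, a tryptophan-degrading enzyme (18.3-fold), NPTX1, a neuronal pentraxin (15.8-fold), RIPOR2 (15.7-fold), GRIA4, a glutamate receptor subunit (log2 -3.81), and CXCL5, a chemokine (10.7-fold). SOX2, a core pluripotency factor, fell by 2.43 on the log2 scale, with an SE of 0.16 (5.39-fold, adjusted p = 1.11e-06). Genes commonly read as Wnt targets differed in size of response: LEF1 rose 5.88-fold (2.56 ± 0.25), SP5 rose 1.77-fold (0.83 ± 0.07), and AXIN2 differed by 0.30 ± 0.12 (adjusted p = 0.0959). Without PS replicate 1 the AXIN2 difference was 0.41 and passed (adjusted p = 0.0270).

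Of the 34 measured primitive streak genes, 31 rose and 0 fell by limma, with 0 falls also at an unadjusted p under 0.05 (32 and 0 adjusted over the list alone), with a median log2 change of 2.69 (camera adjusted p = 1.29e-27, and adjusted p = 0.0260 with an estimated correlation). BMP pathway genes rose in 21 of 25 cases with 0 falls by limma and 0 unadjusted (22 adjusted over the list alone, median 2.10), among them BMPER, a BMP-binding protein (36.7-fold). Their camera adjusted p was 1.22e-22, and adjusted p = 0.00531 with an estimated correlation. Definitive endoderm genes rose in 16 of 20 cases (16 adjusted over the list alone, median 2.05, camera adjusted p = 5.60e-11, adjusted p = 0.0852 with an estimated correlation). Of 25 mesenchymal genes, 17 rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 1.34e-12, adjusted p = 0.0386 with an estimated correlation), including COL5A2, a fibrillar collagen (7.74-fold), and SNAI2, a repressor of epithelial genes (7.12-fold). Amnion and trophectoderm genes, a cell type such media can also produce, rose in 9 of 17 cases and fell in 2 (9 and 2 adjusted over the list alone). TFAP2A, an AP-2 factor, led that group among genes not already named at 38.8-fold (camera adjusted p = 4.13e-05, adjusted p = 0.0565 with an estimated correlation). Mesoderm genes rose in 14 of 29 cases and fell in 3 (14 and 3 adjusted over the list alone), with BMP4, a secreted ligand, 8.91-fold higher (camera adjusted p = 0.000117, adjusted p = 0.199 with an estimated correlation).

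Core pluripotency genes moved the other way: 18 of 24 fell and 2 rose (19 and 2 adjusted over the list alone), with a median of -0.67. FOXD3, a forkhead factor, was 5.84-fold lower and USP44, a deubiquitinase, 5.82-fold lower (camera adjusted p = 9.24e-08, adjusted p = 0.0716 with an estimated correlation). Cholesterol synthesis genes fell in 17 of 19 cases with 0 rises by limma and 0 unadjusted (17 adjusted over the list alone, camera adjusted p = 9.24e-08, adjusted p = 0.199 with an estimated correlation). INSIG1, a sterol-regulated retention protein, was 2.75-fold lower and SQLE, squalene epoxidase, 2.08-fold lower. Of 23 epithelial genes, 14 fell and 3 rose (15 and 4 adjusted over the list alone, camera adjusted p = 0.00175, adjusted p = 0.0716 with an estimated correlation). CLDN3, a tight junction claudin, was 3.45-fold lower, and KRT19, a keratin, was 2.23-fold higher. Neuroectoderm genes fell in 9 of 24 cases and rose in 2 (9 and 2 adjusted over the list alone), with SFRP1, a secreted Wnt antagonist, 6.34-fold lower. That call (camera adjusted p = 0.0126) gave adjusted p = 0.199 with an estimated correlation and was lost without the dimmest genes (0.235).

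Nodal/Activin genes rose in 11 of 20 cases and fell in 2 (13 and 2 adjusted over the list alone), with TGFB1, a TGF-beta ligand, 10.2-fold and NODAL 4.39-fold higher (camera adjusted p = 2.27e-05, adjusted p = 0.0876 with an estimated correlation). Wnt targets rose in 12 of 26 cases and fell in 2 (12 and 2 adjusted over the list alone), with NOTUM, a Wnt deacylase, 16.5-fold higher (camera adjusted p = 0.00239, adjusted p = 0.199 with an estimated correlation). Of 19 Wnt ligands, 4 rose and 0 fell by limma, with 0 falls unadjusted (4 adjusted over the list alone), including WNT3 (14.3-fold) and WNT5A (12.9-fold). The ligand call (camera adjusted p = 0.0400, adjusted p = 0.263 with an estimated correlation) was lost without untreated replicate 1 (0.0523) or PS replicate 1 (0.0776), as deposited (0.0650) and with median centring (0.0601). Immediate early genes rose in 7 of 17 cases and fell in 2 (7 and 2 adjusted over the list alone), with JUN, an AP-1 subunit, 2.43-fold higher. Their call (camera adjusted p = 0.0400, adjusted p = 0.493 with an estimated correlation) was lost without untreated replicate 3 (0.0620) or PS replicate 2 (0.105).

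The other 13 lists did not pass camera in this comparison. Glycolysis and hypoxia genes had 7 rises and 5 falls among 27 (11 and 5 adjusted over the list alone, adjusted p = 0.0677), and passed without untreated replicate 3 (0.0158), PS replicate 2 (0.00852), or doxycycline replicate 2 (0.0433) or 3 (0.0435). They also passed as deposited (0.0319), with median centring (0.0226), over all probe sets (0.0490) and in a fit of the 2 groups alone (0.0464). The others were nuclear oxidative phosphorylation (1 rose and 5 fell of 23, adjusted p = 0.136), naive pluripotency (5 and 2 of 17, 0.232), cell cycle (8 and 4 of 29, 0.232), ATF4 stress (5 and 6 of 28, 0.280) and p53 genes (2 and 3 of 20, 0.295). HOX genes (1 and 0 of 16 by limma, 3 and 0 unadjusted) had an adjusted p of 0.760. Wnt receptors and inhibitors (10 and 9 of 31), TCF/LEF factors with co-repressors (4 and 4 of 19), FGF/ERK (9 and 10 of 25) and interferon genes (6 and 5 of 25) had adjusted p = 0.914. Markers of fibroblasts (4 and 4 of 15) and of endothelium and blood (1 and 3 of 17) had adjusted p = 0.996. Median, mean and test differed in sign for the last 7 lists named here, none of which passed.

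Altogether 5495 of 18417 genes differed between PS medium and untreated cells by limma, 2608 higher and 2887 lower (2766 and 2228 after median centring), and 1039 of them by at least 2-fold. A log offset of 64 in place of 16 lowered the changes of GATA6, GATA4, CER1, HAND1, LRAT, IDO1, RIPOR2 and GRIA4 by over 1.5 times, that of GATA6 to 6.32 on the log2 scale, and an offset of 1 enlarged those of GATA6 (9.96), HAND1 (7.75) and GRIA4 (-4.50).

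**Figure D2:**
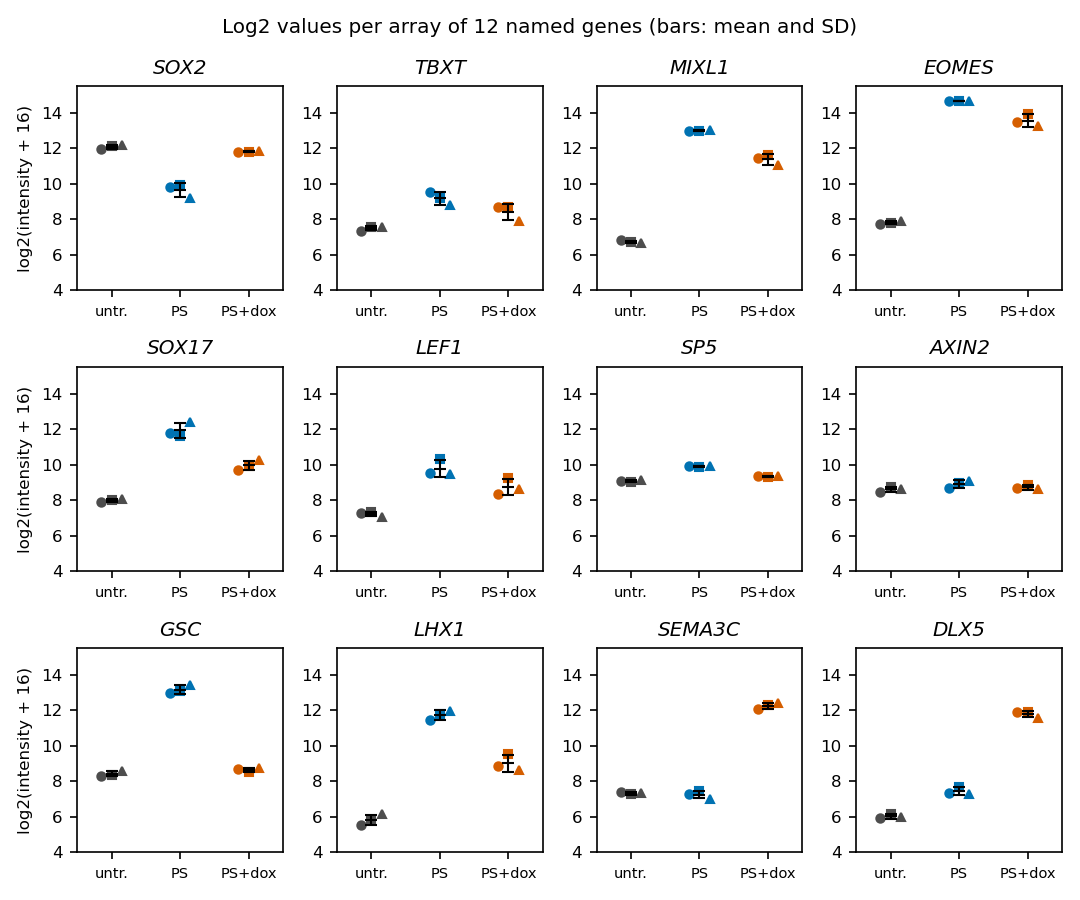
Normalized log2(intensity + 16) of 12 named genes on each of the 9 arrays by group, with the group mean and a bar of 1 SD. MIXL1 was 6.25 higher on this scale in PS medium than in untreated cells and fell by 1.61 with doxycycline, whereas SEMA3C rose 32.1-fold with doxycycline.

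The comparison of PS medium with and without doxycycline addresses the effect of TCF7L1 induction, and no group received doxycycline without the transgene. The largest rise was in CYP24A1, the enzyme that inactivates vitamin D (49.7-fold, log2 5.63 ± 0.37, SE, n = 3 per group, adjusted p = 4.70e-06). SEMA3C, a secreted guidance ligand, rose 32.1-fold (adjusted p = 7.03e-09), CLIC5, an intracellular chloride channel protein, 23.8-fold (4.57 ± 0.19), DLX5, a homeobox factor, 20.3-fold (4.34 ± 0.13), and LRRN3, a leucine-rich repeat membrane protein, 18.9-fold (4.24 ± 0.37). STEAP4, a metalloreductase, rose 24.7-fold, which became 14.2-fold without doxycycline replicate 3 and 39.0-fold without replicate 2. The largest fall was in GSC, a homeobox factor of the embryonic organizer (22.9-fold lower, -4.52 ± 0.12, adjusted p = 8.11e-09). NTN4, a netrin, was 8.57-fold lower, CRHBP, which binds corticotropin-releasing hormone, 7.13-fold, ABCC9, a potassium channel regulatory subunit, 6.73-fold, and LHX1, a LIM homeobox factor, 6.54-fold. UPK1B, a uroplakin, was 7.82-fold lower, or 5.03-fold without PS replicate 3.

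SOX2 rose 4.53-fold with doxycycline (log2 2.18 ± 0.16, adjusted p = 7.74e-06). SOX17 was 3.91-fold lower (-1.97 ± 0.19), MIXL1 was 3.05-fold lower (-1.61 ± 0.12), and SP5 fell by 0.59 on the log2 scale (SE 0.07). EOMES was 2.15-fold lower (-1.10 ± 0.14), or 4.55-fold on values as deposited. The normalized EOMES value was the same on every PS array (SD 0), so that SE leaves out the spread among PS arrays. LEF1 was 2.05-fold lower (-1.04 ± 0.25, adjusted p = 0.0144), a call lost without doxycycline replicate 1 (-0.85, adjusted p = 0.0632). TBXT was 1.72-fold lower (-0.78 ± 0.22, adjusted p = 0.0331). The TBXT call was lost without untreated replicate 1 (-0.78, adjusted p = 0.0503), PS replicate 1 (-0.60, 0.125) or 2 (-0.77, 0.0728), or doxycycline replicate 3 (-0.52, 0.0776), and in a fit of the 2 groups alone (0.0776). AXIN2 differed by -0.18 ± 0.12 (adjusted p = 0.379).

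Primitive streak genes fell in 28 of 34 cases and rose in 1, NOG, a secreted BMP antagonist that rose 6.39-fold (29 and 1 adjusted over the list alone). Their median was -1.12 (camera adjusted p = 5.21e-18, adjusted p = 0.0607 with an estimated correlation), and FGF17, a growth factor, was 5.35-fold lower. Definitive endoderm genes fell in 12 of 20 cases with 0 rises by limma and 1 at an unadjusted p under 0.05 (16 and 1 adjusted over the list alone), with GATA4 3.99-fold lower (camera adjusted p = 2.33e-08, adjusted p = 0.125 with an estimated correlation). Mesoderm genes fell in 8 of 29 cases and rose in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00699, adjusted p = 0.341 with an estimated correlation). MESP2, a factor of presomitic mesoderm, was 4.13-fold lower, whereas ISL1, a LIM homeobox factor, was 16.1-fold higher. Of 25 FGF/ERK genes, 14 fell and 3 rose (15 and 3 adjusted over the list alone, camera adjusted p = 0.000138, adjusted p = 0.112 with an estimated correlation). SPRY4, a feedback inhibitor, was 2.96-fold lower and DUSP6, an ERK phosphatase, 2.80-fold lower.

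Epithelial genes rose in 17 of 23 cases with 0 falls by limma and 0 unadjusted (19 adjusted over the list alone, median 0.57), the list call of this comparison that held with an estimated correlation (camera adjusted p = 1.06e-12, adjusted p = 0.00750 with an estimated correlation). TJP3, a tight junction scaffold, rose 3.08-fold, GRHL2, a grainyhead factor of epithelia, 2.92-fold, CLDN3 2.62-fold and CLDN10 2.53-fold. Mesenchymal genes fell in 13 of 25 cases and rose in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 1.96e-07, adjusted p = 0.0697 with an estimated correlation). COL5A2 was 5.60-fold lower, PDGFRA, a growth factor receptor, 4.02-fold and SNAI1, a repressor of epithelial genes, 3.88-fold, whereas TGFB2 was 4.17-fold higher. Amnion and trophectoderm genes rose in 9 of 17 cases and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 5.89e-05, adjusted p = 0.0607 with an estimated correlation). TFAP2C, an AP-2 factor, rose 2.76-fold and KRT7, a keratin, 3.21-fold.

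ATF4 stress genes, which amino acid shortage and mitochondrial stress are known to raise, fell in 12 of 28 cases with 0 rises by limma and 1 unadjusted (14 and 1 adjusted over the list alone, camera adjusted p = 1.40e-05, adjusted p = 0.150 with an estimated correlation). WARS1, a tRNA synthetase, was 1.94-fold lower and PSAT1, of serine synthesis, 1.70-fold lower. Cholesterol synthesis genes rose in 4 of 19 cases with 0 falls by limma and 0 unadjusted (4 adjusted over the list alone), namely TM7SF2 (2.41-fold), STARD4 (1.83-fold), SC5D (1.31-fold) and SREBF2 (1.29-fold), with camera adjusted p = 5.89e-05 and adjusted p = 0.341 with an estimated correlation. Nuclear oxidative phosphorylation genes rose in 3 of 23 cases with 0 falls by limma, and 10 rose and 0 fell unadjusted (5 adjusted over the list alone, median 0.15, camera adjusted p = 0.000138, adjusted p = 0.0607 with an estimated correlation). Glycolysis and hypoxia genes fell in 6 of 27 cases and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.000156, adjusted p = 0.447 with an estimated correlation), with HK1, a hexokinase, 1.66-fold and PDK1, a pyruvate dehydrogenase kinase, 2.08-fold lower.

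Wnt receptors and inhibitors fell in 10 of 31 cases and rose in 3 (11 and 4 adjusted over the list alone, camera adjusted p = 0.00380, adjusted p = 0.0607 with an estimated correlation), with ROR2, a Wnt5a receptor, 3.46-fold and FZD7, a frizzled receptor, 3.21-fold lower. TCF/LEF factors with co-repressors rose in 6 of 19 cases and fell in 1 (8 and 1 adjusted over the list alone), with TCF7L2, a relative of TCF7L1, 2.10-fold higher. That list includes TCF7L1 itself, and its call (camera adjusted p = 0.0148, adjusted p = 0.259 with an estimated correlation) was lost without PS replicate 1 (0.0590). Wnt targets fell in 8 of 26 cases and rose in 2 (8 and 2 adjusted over the list alone), with APCDD1, a Wnt inhibitor, 2.26-fold lower. Their call (camera adjusted p = 0.0368, adjusted p = 0.351 with an estimated correlation) was lost without PS replicate 2 (0.0918), doxycycline replicate 1 (0.0716) or 3 (0.0921), with median centring (0.0529) and without the dimmest genes (0.0908).

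Of the other 13 lists, which did not pass camera, Nodal/Activin genes (3 rose and 8 fell of 20, 3 and 10 adjusted over the list alone, adjusted p = 0.0586) passed without untreated replicate 3 (0.0446), PS replicate 2 (0.0351) or doxycycline replicate 1 (0.0432). They also passed as deposited (0.0478), with an offset of 64 (0.0492), without the dimmest genes (0.0466), over all probe sets (0.0344) and in a fit of the 2 groups alone (0.0455). Wnt ligands (1 and 3 of 19, 0.0586) passed without PS replicate 3 (0.0312) or doxycycline replicate 3 (0.0375), interferon genes (4 and 7 of 25, 4 and 11 adjusted over the list alone, 0.0586) without PS replicate 2 (0.0170), and p53 genes (0 and 2 of 20 by limma, 0 and 3 unadjusted, 0.394) without PS replicate 3 (0.0405). BMP genes went both ways (10 and 5 of 25, adjusted p = 0.124), as did core pluripotency genes (6 and 5 of 24, 0.797), where PRDM14, a pluripotency factor, rose 2.10-fold and SFRP2, a Wnt antagonist, was 2.34-fold lower. Fibroblast markers (3 and 2 of 15, 0.366), endothelial and blood markers (1 and 1 of 17, 0.396), cell cycle genes (0 and 1 of 29 by limma, 2 and 3 unadjusted, 0.490), immediate early genes (4 and 2 of 17, 0.700) and HOX genes (0 and 1 of 16 by limma, 0 and 1 unadjusted, 0.730) did not pass either. For naive pluripotency (3 and 2 of 17) and neuroectoderm genes (3 and 5 of 24), both at adjusted p = 0.682, median, mean and test differed in sign.

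With doxycycline 3195 of 18417 genes differed from PS medium alone by limma, 1641 higher and 1554 lower (1392 and 1470 after median centring), and 613 by at least 2-fold. Without doxycycline replicate 3, whose TCF7L1 level was low, 2939 genes differed, 2622 of them shared in the same direction. With an offset of 64 the log2 changes were smaller for CYP24A1 (4.70), STEAP4 (3.56), CLIC5 (3.69), ISL1 (3.38) and ABCC9 (-2.03), and with an offset of 1 that of STEAP4 was 5.30.

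**Figure D3:**
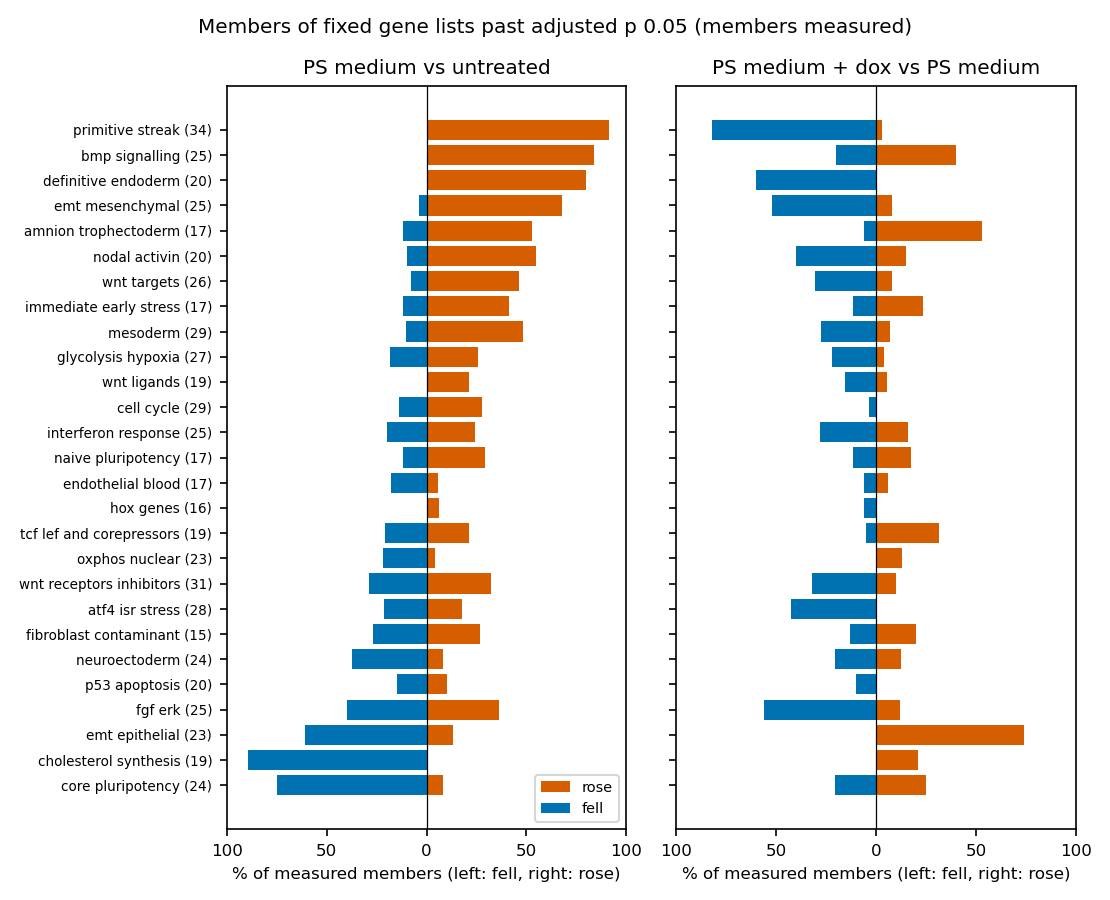
Percent of the measured members of each of 27 gene lists that rose (right of 0) or fell (left of 0) past adjusted p 0.05 over all genes, for PS medium against untreated cells and for PS medium with doxycycline against PS medium alone; the number measured is in brackets. Primitive streak genes had 31 rises of 34 in the first comparison and 28 falls of 34 in the second.

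The comparison of PS medium with doxycycline against untreated cells gives the differences between those 2 groups. HPGD, which degrades prostaglandins, rose 94.3-fold (log2 6.56 ± 0.20, SE, n = 3 per group, adjusted p = 6.17e-09). GATA6 rose 90.3-fold, TFAP2A 87.1-fold (6.44 ± 0.15) and CER1 81.9-fold. TBX3, a T-box factor, rose 79.2-fold, and GATA3, a zinc finger factor, 77.8-fold (6.28 ± 0.12). GATA6 and TBX3 were dim in untreated cells. With log offsets of 64 and 1 the folds were 28.1 and 343 for GATA6, and 28.2 and 199 for TBX3. The largest falls were LRAT (25.3-fold lower), NPTX1 (16.2-fold), CYP2B6, a drug-metabolising cytochrome (15.1-fold), DUSP6 (13.7-fold), TM4SF18, a membrane protein (12.4-fold), and EDNRB, an endothelin receptor (10.4-fold). EOMES stayed 53.5-fold, MIXL1 24.9-fold, SOX17 3.94-fold, LEF1 2.86-fold and TBXT 1.86-fold above untreated cells (adjusted p = 0.0104 for TBXT). SOX2 differed from untreated cells by -0.25 ± 0.16 on the log2 scale (adjusted p = 0.263), which passed without PS replicate 3 (-0.25, adjusted p = 0.0195) and in a fit of the 2 groups alone (0.0181). AXIN2 differed by 0.11 ± 0.12 (adjusted p = 0.549). SP5 rose 1.18-fold (0.24 ± 0.07, adjusted p = 0.0211), a call lost without untreated replicate 1 (0.24, adjusted p = 0.0705) or 2 (0.20, 0.0886), or doxycycline replicate 1 (0.23, 0.0621) or 3 (0.23, 0.0583).

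BMP genes rose in 22 of 25 cases with 0 falls by limma and 0 at an unadjusted p under 0.05 (23 adjusted over the list alone, median 2.65), with NOG 67.8-fold and MSX2, a BMP-responsive homeobox factor, 61.6-fold higher (camera adjusted p = 4.52e-23, adjusted p = 0.00485 with an estimated correlation). Amnion and trophectoderm genes rose in 9 of 17 cases with 0 falls by limma and 0 unadjusted (9 adjusted over the list alone, camera adjusted p = 2.53e-08, adjusted p = 0.0271 with an estimated correlation). Primitive streak genes rose in 23 of 34 cases (24 adjusted over the list alone, median 1.21, camera adjusted p = 5.36e-14, adjusted p = 0.0845 with an estimated correlation) and mesenchymal genes in 17 of 25 (17 adjusted over the list alone, camera adjusted p = 3.92e-07, adjusted p = 0.0946 with an estimated correlation). FN1, fibronectin, rose 8.01-fold. Definitive endoderm genes rose in 9 of 20 cases and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 3.02e-05, adjusted p = 0.243 with an estimated correlation). Epithelial genes rose in 10 of 23 cases and fell in 3 (12 and 4 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.138 with an estimated correlation), with KRT8, a keratin, 2.28-fold higher and ITGA6, a laminin receptor subunit, 2.62-fold lower.

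Core pluripotency genes fell in 16 of 24 cases and rose in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 2.53e-08, adjusted p = 0.0845 with an estimated correlation), with USP44 5.26-fold and POLR3G, an RNA polymerase III subunit, 4.38-fold lower. ATF4 stress genes fell in 17 of 28 cases and rose in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 2.85e-05, adjusted p = 0.193 with an estimated correlation), with CHAC1, a glutathione-degrading enzyme, at -1.59 and SLC7A11, the cystine transporter, at -1.22 on the log2 scale. Neuroectoderm genes (10 fell and 3 rose of 24, 10 and 3 adjusted over the list alone, camera adjusted p = 0.00323, adjusted p = 0.193 with an estimated correlation) and FGF/ERK genes (12 fell and 3 rose of 25, 14 and 6 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.243 with an estimated correlation) also passed. Cholesterol synthesis genes fell in 5 of 19 cases and rose in 2 (8 and 2 adjusted over the list alone), a call (camera adjusted p = 0.0233, adjusted p = 0.488 with an estimated correlation) lost without doxycycline replicate 3 (0.0527). Nodal/Activin genes rose in 9 of 20 cases and fell in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00423, adjusted p = 0.243 with an estimated correlation). TCF/LEF factors with co-repressors rose in 7 of 19 and fell in 1 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.254 with an estimated correlation, lost over all probe sets at 0.0507). Immediate early genes rose in 6 of 17 and fell in 1 (6 and 2 adjusted over the list alone, camera adjusted p = 0.0342, adjusted p = 0.420 with an estimated correlation). The immediate early call was lost without untreated replicate 3 (0.0723) or doxycycline replicate 2 (0.110), and without the dimmest genes (0.0613).

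The 13 lists that did not pass had adjusted p from 0.0672 to 0.815. Mesoderm genes (8 rose and 3 fell of 29, 0.0672) passed without untreated replicate 3 (0.0279) or doxycycline replicate 1 (0.0310) or 2 (0.0400). Wnt targets (11 and 5 of 26, 0.0672) passed without doxycycline replicate 1 (0.0437) or 3 (0.0253) and without the dimmest genes (0.0387). Without doxycycline replicate 3, p53 genes (1 and 8 of 20, 0.124) and glycolysis and hypoxia genes (4 and 5 of 27, 0.398) passed at adjusted p = 0.0440, and naive pluripotency genes (5 and 2 of 17, 0.124) passed without the dimmest genes (0.0379). Wnt receptors and inhibitors (7 and 9 of 31, 0.519) had a negative median with a positive mean. In this comparison 5572 of 18417 genes differed by limma, 2826 higher and 2746 lower (2915 and 2275 after median centring), and 958 by at least 2-fold. Without doxycycline replicate 3 the count was 4969, 4657 of them shared in the same direction. Offsets of 1 and 64 moved GATA6 to 8.42 and 4.81 and TBX3 to 7.64 and 4.82 on the log2 scale. The same offsets moved CYP2B6 to -4.58 and -2.88 and TM4SF18 to -4.34 and -2.59. An offset of 64 also moved HPGD (5.91), CER1 (5.74), GATA3 (5.48), MSX2 (5.24) and LRAT (-3.80).

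Genes that rose at least 2-fold in PS medium were then followed under doxycycline. Of these 557 genes, 327 (58.7%) were lower and 55 (9.87%) higher with doxycycline than in PS medium alone, and the median gene kept 61.2% of its log2 induction. By doxycycline array the median was 56.4%, 63.7% and 61.1% (SD 3.73, n = 3). The share depended on the fold minimum: 828 of 2608 genes were lower with no minimum, and 120 of 190 with a 4-fold minimum. GSC kept 4.62% of its log2 induction, NTN4 2.05%, COL5A2 15.9%, PDGFRA 43.1%, SOX17 50.2% and MIXL1 74.2%. At the other end HAND1 kept 92.4% and BMP4 102%, and GATA3 (121%), TFAP2A (122%), TFAP2C (192%) and HPGD (234%) exceeded the level of PS medium alone. Of the 482 genes that fell at least 2-fold in PS medium, 188 (39.0%) were higher and 47 (9.75%) lower with doxycycline, and the median gene kept 80.9% of its log2 change. In 20 simulated data sets with no doxycycline effect, 0 genes of either set were called by limma, and the medians kept were 99.3% and 98.3%. With no effect on any gene the adjustment leaves almost no calls, so that 0 is not a chance count for the 327 and 188. The simulated genes also varied independently of each other. The difference between both sets in the share kept was not tested.

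**Figure D4:**
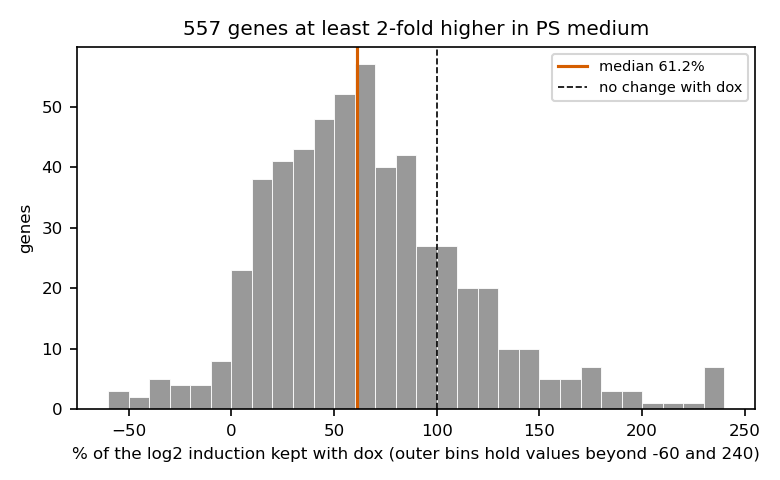
Histogram of the percent of the log2 induction by PS medium that was kept with doxycycline, for the 557 genes that rose at least 2-fold in PS medium. The line marks the median of 61.2%.

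Because both comparisons use the PS arrays with opposite sign, their log2 changes correlate across genes without any effect. The observed r across genes was -0.39, against -0.50 simulated with no effect, and the covariance was -0.0887 against -0.00652 simulated, a difference of -0.0822. Of genes called in both comparisons, 1584 moved in opposite directions and 384 in the same direction, against 477 and 476 for independent lists. For PS medium with and without doxycycline, each against the same untreated arrays, r was 0.75 against 0.50 simulated, and the covariance was 0.233 against 0.00645. In those comparisons 3392 genes were called in the same direction and 142 in opposite directions, against 831 and 832 for independent lists. With 3 arrays per group the shared arrays could not be split into parts of at least 2, so part of the excess may come from shared arrays, and genes are not independent replicates.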

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

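The tests of doxycycline replicate 3, of the genes at intermediate levels and of doxycycline itself were chosen only after the result was seen. The splits of the arrays were planned.

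A signal also appeared in probe sets that the comparisons left out. With doxycycline in PS medium, 121 of 12083 probe sets with no gene symbol listed changed by limma at adjusted p under 0.05 (39 higher and 82 lower, 1.00%). Of the 1754 probe sets with several symbols, 172 changed (70 higher and 102 lower, 9.81%). Each class was fitted and adjusted on its own. Among the genes tested in the same comparison 3195 of 18417 changed (17.3%), a larger share than in either class.

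Each comparison of 3 arrays with 3 makes 10 splits, which cannot give a share under 0.05, and 1 split of the 10, the real one, gave as many genes in each comparison. By limma the real counts were 5495 for PS medium against untreated cells, 3195 for doxycycline against PS medium and 5572 for doxycycline against untreated cells, with a highest count of 0 for any other split in each. At an unadjusted p under 0.05 the real counts were 7163, 5212 and 7313. Other splits gave 123 to 1258, 226 to 1754 and 111 to 712. Every other split puts arrays of both groups on each side, so the group difference enters its spread and can lower its counts. Counts of other splits are therefore not those of data without an effect. Where the numbers pair the samples, 4 of the 10 splits part all 3 pairs, the real one included, and the highest count was 0 both among the others that do so and among those that do not.

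TCF7L1 on doxycycline replicate 3 was 4.73-fold below the mean of replicates 1 and 2 in deposited intensity, and 7 other genes of 18417 differed at least as much on that array. A sample of another group is argued against, because its lowest correlation with its own group exceeded its highest with any other array by 0.0183. The SD of its differences from its group was 0.230, within the 0.130 to 0.246 of the other arrays. That was 1.31 times their median and under a bound of 1.5, which was set after the result was seen. A large fault of the whole array was therefore not seen, but a smaller one stays open. A weaker response of the other genes is argued against by a held-out share of 95.6%, against 88.9% and 99.2% for the other replicates. A fault of the TCF7L1 probe set alone stays open, since there was only 1 probe set for TCF7L1. Weaker induction of the transgene in that sample, which the design allows, was not tested and stays open.

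Of the 557 PS-induced genes, 245 kept 25% to 75% of their log2 induction with doxycycline, and so lay between untreated cells and PS medium. Another 102 kept less and 210 kept more. Some genes outside that range also lay between, such as GSC (4.62%) and HAND1 (92.4%), whereas others, such as HPGD (234%), lay above PS medium. A mixture of untreated-like and PS-like cells as the whole cause is argued against by 200 of the 613 genes changed at least 2-fold with doxycycline (32.6%), which lay beyond both other groups by at least 2-fold, 154 above and 46 below. Loss of a common log2 share in every PS-induced gene is argued against: 57.3% of them lay over 3 standard errors from that share. An equal loss on the linear scale would give unequal log2 shares, and was not tested. Induction of the transgene, which the design names, stays among the open explanations and may act on only part of the response.

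Genes changed with doxycycline could also reflect the drug. Mitochondrial stress from doxycycline was examined through ATF4 genes. Of 28, 12 fell and 0 rose by limma (16 and 1 at an unadjusted p under 0.05, 14 and 1 adjusted over the list alone). No net rise was therefore seen, but a fall through TCF7L1 induction could hide a rise from the drug. These values cannot decide the question. The list fell by camera (adjusted p = 1.40e-05, adjusted p = 0.150 with an estimated correlation), so the fall of the list as a whole depends on the correlation used. Another effect of doxycycline itself cannot be told apart from TCF7L1 induction, because 0 groups of cells without the transgene were measured, so the effects of TCF7L1 and of the drug are confounded here. Across the doxycycline arrays the held-out share did not follow measured TCF7L1. It was 95.6% at an intensity of 2699 (replicate 3), 88.9% at 12433 (replicate 2) and 99.2% at 13100.2 (replicate 1). With 1 array of low TCF7L1 and 1 probe set for it, these values cannot decide between TCF7L1 and the drug.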

How the results depend on the processing

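Under the alternatives run, no called named gene changed direction, and the cause of a shift was not tested unless stated. Among 160 main values under alternatives other than leaving out an array, 143 stayed within their limits, 4 passed the threshold newly and 13 moved. Of 1053 list values, 45 lost the call, 26 gained it and 1 reversed. Of 3333 values of named genes, 40 lost the call, 2 gained it and 0 reversed. TCF7L1 in PS medium against untreated cells passed at -1.33 as deposited and at -1.35 without the dimmest genes, in a fit of the 2 groups alone and with the replicate block (adjusted p = 0.0306). A 2-fold minimum gave 1039, 613 and 958 genes in PS medium against untreated cells, doxycycline against PS medium and doxycycline against untreated cells, since it admits fewer genes. An estimated correlation left 3, 1 and 2 of 14, 14 and 14 lists. With fry 18, 17 and 20 passed, which gave 14 of the 26 gained list calls. Fry tests a list against no change and camera tests it against the other genes, so their counts answer different questions. Fry gave fibroblast markers in PS medium an upward direction (adjusted p = 0.0171) and camera a downward one, with a median log2 change of -0.10 and a mean of 0.13. With PS-induced genes defined by 4-fold, 120 of 190 were lower with doxycycline (66.8% kept), and 828 of 2608 with no fold minimum (70.7% kept). For PS-repressed genes these were 26 of 71 (89.4% kept) and 756 of 2887.

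Leaving out each array in turn moved TCF7L1 between -1.42 and -1.26 in PS medium against untreated cells, 1.99 and 3.14 in doxycycline against PS medium, and 0.64 and 1.78 in doxycycline against untreated cells. Counts ran from 4160 to 5633, 2404 to 3074 and 4165 to 6026, and lists from 13 to 15, 13 to 16 and 14 to 16. PS-induced genes lower with doxycycline ranged from 275 to 358 (57.6% to 65.4% kept) and PS-repressed genes higher from 168 to 216 (74.6% to 84.2% kept). Of 2754 such values of named genes 138 lost the call and 2 gained it, and of 729 list values 11 lost it and 18 gained it.

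The replicate number as a block gave 6935, 4481 and 7055 genes, with 5483, 3190 and 5567 shared in the same direction with the planned fit. In the paired comparisons it changed the call of no named gene or list. In PS medium against untreated cells same-number correlations were 0.0857, 0.397 and 0.271. The first lay under 0.1, so the numbers were not taken to pair these samples. Pairing is not excluded there, since pairing the doxycycline samples with both other groups would pair these too. Moreover, 9 of 9 arrays correlated best with their own number, a hint from the data. There AXIN2 (adjusted p = 0.0277) and glycolysis genes (0.0252) passed with the block. Dim genes are limited by signal over background: an offset of 1 moved 18 of 309 named values by over 1.5 times and an offset of 64 moved 46.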

Other observations

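The gene families described here were grouped and tested only after the data were seen, and the genes named here outside the fixed rule were chosen after their values were seen.

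Metallothioneins, small proteins that bind zinc and copper, were lower in PS medium. Of 11 measured members that code for protein, 10 fell against untreated cells by limma, also as deposited and with median centring, led by MT1H (log2 -3.15 ± 0.31, SE, n = 3 per group, adjusted p = 2.32e-05) and MT1G (-2.74 ± 0.41), with MT2A at -1.80 ± 0.25. MT3, a neural member, differed by 0.12 (adjusted p = 0.369). With doxycycline 10 were lower than in untreated cells, and 0 differed from PS medium alone by limma (0 at an unadjusted p under 0.05). Among 331 families of at least 8 members, camera gave this one, tested by symbol as 15 members with 4 pseudogenes, adjusted p = 2.12e-06 in PS medium, and adjusted p = 1.00 with an estimated correlation. Near-identical copies share sequence, so these members are not independent measurements.

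Of 11 measured annexins, which bind membranes in the presence of calcium, 4 rose in PS medium by limma, also as deposited and with median centring. They were ANXA6 (0.99 ± 0.11), ANXA2 (0.84 ± 0.12), ANXA5 (0.33 ± 0.07) and ANXA1 (1.76 ± 0.50, adjusted p = 0.0223). The ANXA1 call was lost without untreated replicate 1 (1.57, adjusted p = 0.0871) or 3 (1.73, 0.0634), or PS replicate 2 (1.22, 0.0659). The family was tested by symbol as 17 members (camera adjusted p = 0.00254, adjusted p = 1.00 with an estimated correlation), and 6 of its 10 risers were not annexins but 3 ANXA2 pseudogenes and 3 genes named for the annexin A2 receptor.

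Some genes stood far above PS medium alone with doxycycline. RARB, a retinoic acid receptor, was 3.85 ± 0.39 above PS medium and 3.87 ± 0.39 above untreated cells on the log2 scale, or 3.24 and 3.26 without doxycycline replicate 3. GPRC5A was 3.85 ± 0.10 above PS medium. SGCZ, a sarcoglycan, was 4.23 ± 0.16 above PS medium. On doxycycline replicate 3, the array with low TCF7L1, CYSLTR2 was 3.41 and RELN 2.80 above the mean of replicates 1 and 2 on the log2 scale.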
